A study of Homo sapiens with 6 samples.

How the data were processed

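The series compared SW480 cells, an established human cell line from a colon adenocarcinoma, after infection with a lentivirus carrying TIPE (the gene TNFAIP8) or with the empty vector, followed by puromycin selection. Per the labels' protocols, poly(A) RNA was isolated, fragmented, reverse transcribed with random primers and sequenced as paired-end libraries. Of the 6 libraries, 3 carried the empty vector and 3 overexpressed TIPE. The group of each library was taken from the treatment label and its replicate number from the sample title. The labels do not say that the libraries of a group came from separate infections or cultures, so every p-value measures the spread between these libraries, which may be technical.

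The authors deposited 1 table of 60605 Ensembl genes. Per the file headers, it holds a count and an FPKM value for each gene and library, beside the exonic gene size, chromosome, start, end, strand, gene symbol and description. The deposited counts were whole numbers with a different total in each library and were taken as raw. The deposited FPKM values were the count per kilobase of exonic gene size, scaled by the total count of that library. Every FPKM value was matched within 0.005 by that formula. Alignment with HISAT2 2.0.1 to hg38 is given per the submitters' processing notes. The counting tool, the annotation release and whether the counting used strand are not given in the sources used here. A gene overlapping another on the opposite strand, a processed pseudogene or a close paralog was therefore treated as uncertain. The table gives no gene biotype. Biotypes and the GC content of the longest transcript came from GENCODE release 29, which held 58337 of the gene identifiers. Of those, 55540 had both ends within 1000 bp of the deposited coordinates. Coordinates are printed as deposited, on hg38.

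The design had been written for FPKM values, with limma on log2(FPKM + 1) as its test and edgeR's quasi-likelihood test in its place if raw counts were present. Counts were present, so edgeR gave the reported results and limma became an alternative. Genes with a mean FPKM of at least 0.5 over the 6 libraries were kept, which left 14192 genes, and library sizes were adjusted by TMM factors of 0.962 to 1.03. The model held the group alone, and p-values from edgeR 4.0.16 were two-sided and adjusted by the Benjamini-Hochberg method. A gene passed the threshold at an adjusted p under 0.05. Standard errors of log2 fold changes were the absolute fold change divided by the square root of the F statistic. TGFB2, TGFB3, TNFAIP8L2 and TNFAIP8L3 lay under the expression filter and were taken from a fit of the same kind without it. R 4.3.3, limma 3.58.1 and DESeq2 1.42.0 were also used.

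Total counts ranged from 13957349 to 20345330 per library, and a count of 0 allows up to 3 counts, or 0.147 to 0.215 CPM. Intervals computed from counts cover counting error only. The edgeR test was tested on simulated data for 14192 genes, 3 libraries against 3, with 200 genes changed. It recovered 54% of the genes changed by a fold of 1.25, 84% of those changed by 1.5, 90% of those changed by 2 and 98% of those changed by 4. Unchanged genes made up 4.68% of its calls. The simulated counts followed the test's own model and held no GC trend. They also had 200 changed genes, against 5903 past the threshold in these data. These rates therefore need not hold here. No columns were identical, and libraries of the same group differed by more than sampling noise, with a chi-square per gene of 2.24 to 7.64 over genes with at least 20 counts, against 21.8 to 39.3 between groups.

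The design, the gene lists, the rule for naming genes and 19 of the alternatives below were chosen before the data were examined. There were 43 lists, covering TGF-beta signalling, secreted factors acting on macrophages, epithelial and mesenchymal genes, signalling targets, metabolism, the cell cycle, stress responses, markers of other cell types and signs of RNA quality. The 38 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The version with an estimated correlation also takes its degrees of freedom from the 6 libraries rather than from the genes tested. A call lost there therefore need not reflect correlated members. The estimate was under 0.01 for the called HIF, WNT, ERK/MAPK, mesenchymal and protease lists. Fry asks whether members changed at all, without comparing them with other genes. Camera p-values were adjusted over the 38 lists. Counts of members are given over all genes tested and adjusted over the list alone. The genes named were TNFAIP8 and its paralogs with TGFB1, TGFB2 and TGFB3, then the 12 genes with the largest increase and the 12 with the largest decrease. These 24 had to have a symbol, pass the threshold, reach a mean FPKM of 1 in the higher group and show no overlap between the groups. From each list discussed, up to 4 members past the threshold with the smallest adjusted p were named, or the 2 most expressed where fewer than 2 passed. Other members are named where a count was small, and these were chosen after their values were seen. Some genes that the rule names are not reported here.

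The 19 alternatives fixed in advance, of 24, were other pseudocounts, expression filters, scalings, limma settings and edgeR's robust option, a replicate block, and the omission of each library in turn. The other 5 were added after seeing the data: DESeq2, removal of each library's trend on GC content alone, removal of its trend on GC content and exonic length, library totals with no factors, and protein-coding genes by GENCODE. The trends were natural splines with 5 degrees of freedom, fitted per library and used as offsets, and 14102 of the tested genes had a GC value. Other pseudocounts, quantile normalization, rescaling to the same FPKM total, trend=FALSE and array quality weights were used in limma alone. Median-ratio scaling was used in limma and in edgeR. A value given for a limma setting thus differs from the edgeR result in the test as well. In simulated data with a GC trend added, the uncorrected test called 7018 unchanged genes and the corrected test 5. The same GC values served to add and to remove that trend, and its size was set rather than estimated from these data. These counts therefore measure neither the false calls here nor how fully the real trend was removed.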

Results

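Gene expression was measured by poly(A) RNA sequencing in SW480 colon cancer cells that carried an empty lentiviral vector (n = 3 libraries) or overexpressed TIPE, the common name of TNFAIP8, a cytosolic protein induced by TNF (n = 3 libraries). Total counts were 15300874, 19496484 and 14472231 in vector replicates 1, 2 and 3, and 16395205, 20345330 and 13957349 in TIPE replicates 1, 2 and 3. The first principal component of the log2 CPM values held 51.8% of the variance and separated the groups. The biological coefficient of variation within groups was 0.0549.

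The comparison of TIPE with vector libraries asks what the overexpressed gene changes in the tumour cell, with TGFB2 and signals to macrophages as the question of the series title. Of 42 genes listed as secreted factors acting on macrophages, 17 were measured and 12 rose in TIPE libraries. Of 23 measured NF-kappaB target genes, 12 rose. Among these were ANGPT2, CXCL1, CXCL8, CCL20 and TNFAIP2, with CXCL1, CXCL8 and CCL20 in both lists. Of the epithelial junction genes 12 of 19 fell, with E-cadherin (CDH1) 2.50-fold lower, as did 21 of 29 genes of mitosis. All 42 measured cytosolic ribosomal protein genes and 19 of 23 glycolysis genes were higher. TGFB1 rose 1.47-fold, while TGFB2 stayed near the detection limit in both groups.

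The overexpressed gene itself, TNFAIP8 (ENSG00000145779, chromosome 5, 119268692 to 119399688, hg38), was at 1.05 ± 0.263 FPKM in vector libraries and at 576 ± 48.3 FPKM in TIPE libraries (SD, n = 3 each). Its counts were 175, 158 and 104 in the vector libraries and 87318, 98811 and 62902 in the TIPE libraries. The log2 fold change was 9.18 with a standard error of 0.12, a fold of 579 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.12e-22). TNFAIP8 took 0.451% to 0.533% of all counts in the TIPE libraries. The deposited FPKM divides by 8506 bp of exon, and the length of TNFAIP8 carried by the vector is not given in the sources used here. Among its paralogs, TNFAIP8L1 had a log2 fold change of 0.26 (adjusted p = 0.10), which was 0.36 without vector replicate 3 (adjusted p = 0.0429, the lowest over the alternatives, which reached 0.572). Of the 2 measured members of the family, 1 rose, or 2 when adjusted over the list alone. TNFAIP8L1 overlaps MYDGF on the opposite strand. TNFAIP8L2 and TNFAIP8L3 had 0 to 2 counts per library and did not pass the test (edgeR adjusted p = 0.662 and 0.914).

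TGFB2 (ENSG00000092969, chromosome 1, 218345336 to 218444619), which encodes a ligand of the TGF-beta receptor, had 3, 3 and 0 counts in the vector libraries and 8, 16 and 4 counts in the TIPE libraries. The ratio of the summed counts, 28 against 6, each over the summed total counts of its group, was 4.54 with a 95% counting interval of 1.84 to 13.4. In the edgeR fit without an expression filter its log2 fold change was 2.16 with a standard error of 0.72 (adjusted p = 0.0159). The call was lost without vector replicate 3 (log2 fold change 1.66, adjusted p = 0.104) and without TIPE replicate 2 (1.69, adjusted p = 0.259). It was also lost in limma on the log2(FPKM + 1) scale (adjusted p = 0.162), and over all alternatives the adjusted p for TGFB2 ranged from 0.00684 to 0.259. TGFB1 (ENSG00000105329, chromosome 19, 41301587 to 41353922), the most expressed of the TGF-beta ligands here, rose from 50.4 ± 3.44 to 70.6 ± 3.61 FPKM (SD, n = 3 each). Its log2 fold change was 0.56 with a standard error of 0.06 (edgeR adjusted p = 9.15e-07), and 0.32 with the GC and length trend of each library removed (adjusted p = 0.000174). TGFB1 overlaps HNRNPUL1, CCDC97 and TMEM91 on the opposite strand and ENSG00000286177 on the same strand. Whether the counting used strand is not given, so the reads of these genes may not be told apart where they overlap. TGFB3 had a log2 fold change of -0.33 (adjusted p = 0.590).

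**Figure D1:**
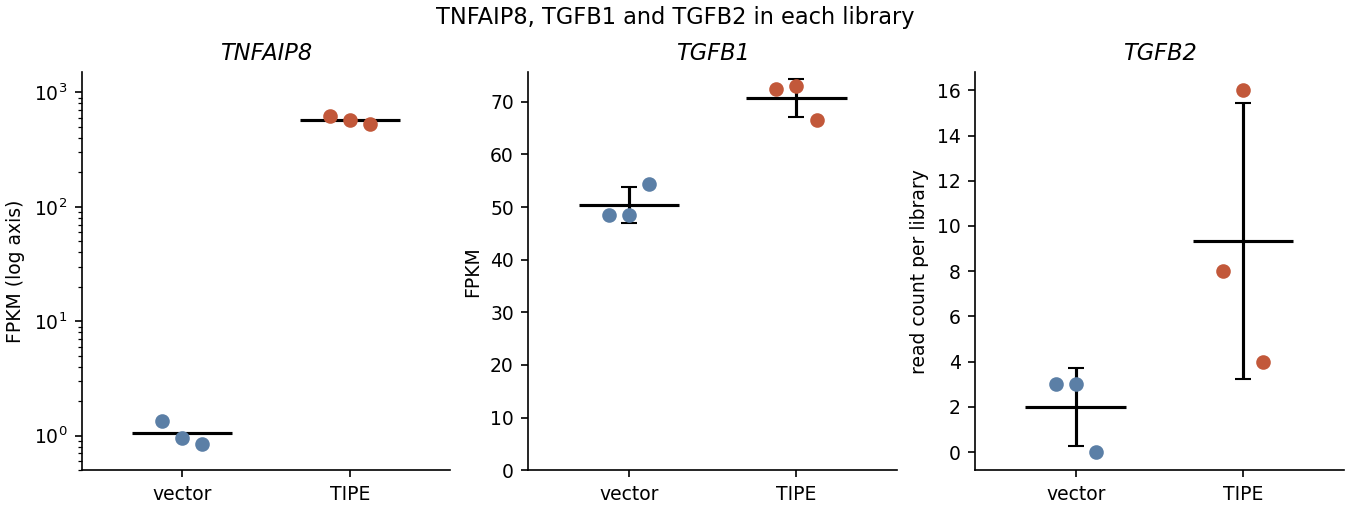
Values of TNFAIP8 (FPKM, log axis), TGFB1 (FPKM) and TGFB2 (read count) in each of the 3 vector and 3 TIPE libraries. Points are libraries, the wide horizontal line is the group mean, and bars in the TGFB1 and TGFB2 panels are 1 SD; TGFB2 reached at most 16 counts in a library.

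Of 10 measured TGF-beta ligands, receptors and latency proteins, 3 rose (TGFB1, LTBP3 and LTBP4) and 1 fell (TGFBR1). The counts adjusted over the list alone were the same. LTBP3, which anchors latent TGF-beta in the matrix, had a log2 fold change of 0.42, LTBP4 one of 0.19 and the receptor TGFBR1 one of -0.38. The call of LTBP4 was lost without vector replicate 1, without vector replicate 2 and without TIPE replicate 2 (adjusted p = 0.0828, 0.0974 and 0.138), and its log2 fold change was -0.025 with each library's GC trend removed (adjusted p over the alternatives, 0.000215 to 0.792). TGFBR1 was at -0.19 with the GC and length trend removed (adjusted p = 0.0614, the highest over the alternatives). The list was not called by camera (adjusted p = 0.629), and its median of -0.06 differed in sign from its mean of 0.04 and from the test, which leaned higher. Of 26 measured TGF-beta/SMAD target genes, 10 rose and 5 fell (adjusted over the list alone, 10 and 6), with a list median of 0.12 and no camera call (adjusted p = 0.118). The directional fry test, which does not compare members with other genes, did pass this list, toward higher (fry adjusted p = 0.0120). That is not particular to TGF-beta targets. Fry also passed other lists that camera did not call, among them p53 targets, S phase and cholesterol synthesis (fry adjusted p = 0.0148, 0.0151 and 0.0151). TGFBI, an extracellular matrix protein, had a log2 fold change of 0.58 and ID1, an inhibitor of DNA binding by bHLH factors, one of 0.75. PMEPA1, a feedback inhibitor of the pathway, had one of -0.33. The other members that fell were CCN1, FN1, SNAI2 and TPM1.

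Over all genes, 5903 of 14192 passed the threshold, 41.6% of those tested, with 2967 higher and 2936 lower in TIPE libraries. The median absolute log2 fold change of these genes was 0.35, and 205 of them changed at least 2-fold, 136 upward and 69 downward. Without TIPE replicate 1, 108 genes fell at least 2-fold. The 2 groups did not overlap at 50.9% of the tested genes, against the 10% that chance gives for 3 against 3. On the deposited FPKM scale without TMM factors, limma called 1911 genes higher and 3240 lower. With each library rescaled to the same FPKM total it called 1308 higher and 4073 lower, with a median log2 fold change of -0.13 over all genes. Fold changes also followed GC content. The median log2 fold change was -0.21 over the 2821 genes of lowest GC content and 0.19 over the 2820 of highest. With each library's trend on GC content and exonic length removed, 4866 genes passed, 3780 of them shared with the uncorrected test in the same direction. The 762 measured genes of chromosome 7 lay below all other genes, with a difference in corrected median log2 fold change of -0.11 (95% bootstrap interval -0.12 to -0.07). Chromosomes 16, 19 and 17 lay above the other autosomes, by 0.07, 0.04 and 0.02.

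**Figure D2:**
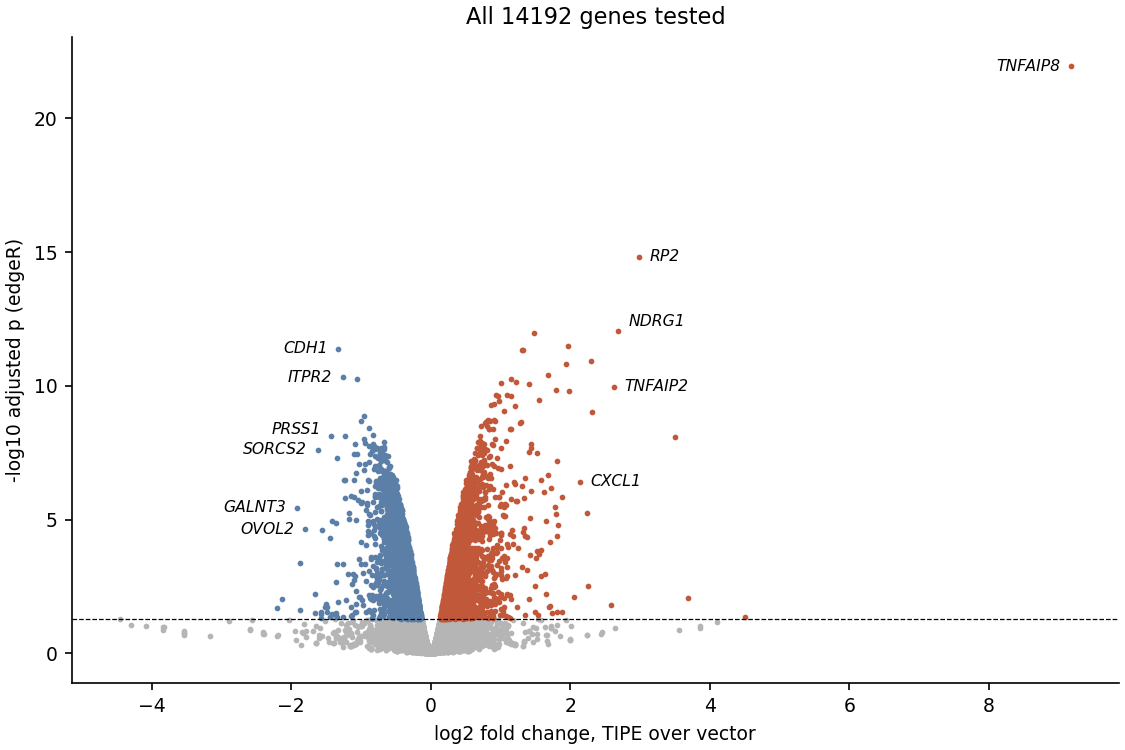
Each point is 1 of the 14192 genes tested, with its log2 fold change (TIPE over vector) on the x axis and the -log10 of its edgeR adjusted p on the y axis. The dashed line marks an adjusted p of 0.05, coloured points passed it (2967 higher, 2936 lower), and TNFAIP8 stands apart at a log2 fold change of 9.18.

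**Figure D3:**
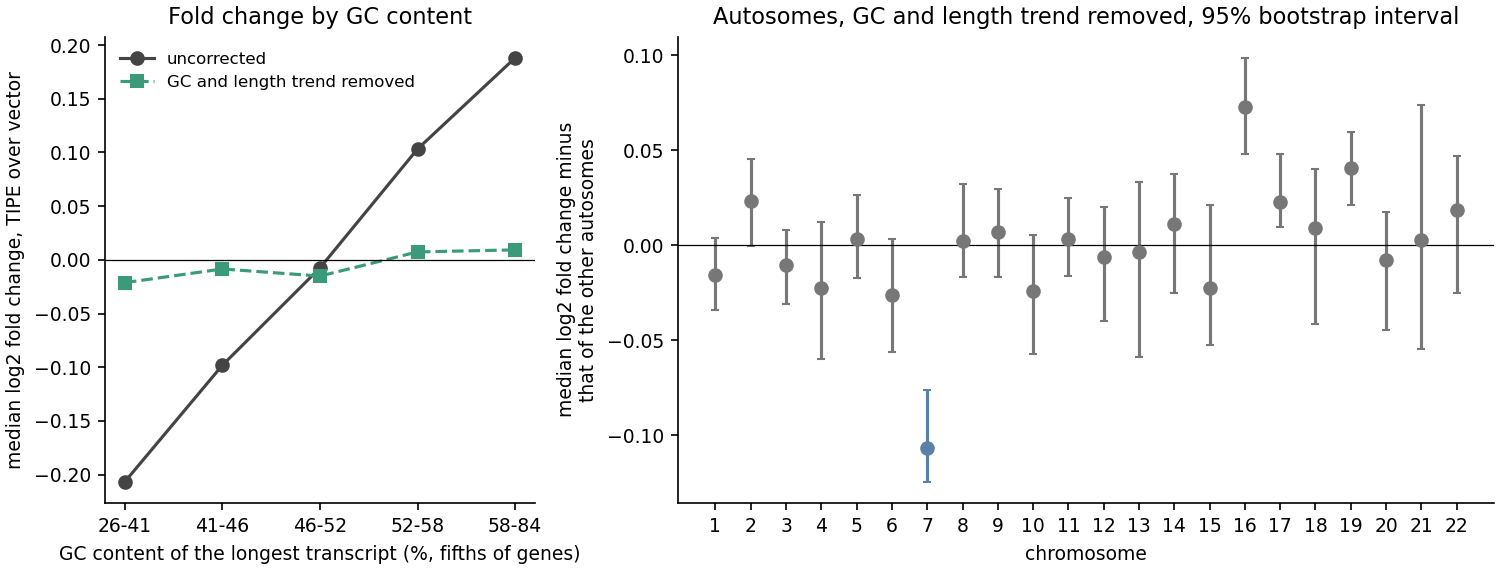
Left, the median log2 fold change (TIPE over vector) of genes in bins of GC content, as tested and with the GC and length trend of each library removed; the uncorrected medians run from -0.21 to 0.19. Right, for each autosome the corrected median minus that of the other autosomes, with a 95% bootstrap interval over genes; chromosome 7 is lowest at -0.11 and chromosome 16 highest at 0.07.

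Among the genes that met the naming rule, the largest rise apart from TNFAIP8 and the scarce transcript GLIS2-AS1 was in RP2 (ENSG00000102218, chromosome X, 46837043 to 46882358). RP2 encodes a GTPase-activating protein for ARL3. RP2 went from 5.74 ± 0.322 to 43.3 ± 6.81 FPKM (SD, n = 3 each), a log2 fold change of 2.98 with a standard error of 0.09 (edgeR adjusted p = 1.50e-15). NDRG1, a gene induced by hypoxia, rose 6.43-fold to 2.98 ± 0.0778 FPKM, and TNFAIP2, a TNF-induced gene, rose 6.17-fold to 2.19 ± 0.0459 FPKM. The neurotrophin receptor NGFR, the basement membrane protein FREM1 and the phosphoglucomutase-like PGM5 had log2 fold changes of 1.94, 1.97 and 1.98. SYT13, an atypical synaptotagmin, rose 4.93-fold, and SRARP, a regulator of steroid receptors, 4.98-fold. The antisense transcripts GLIS2-AS1 and MYG1-AS1 had log2 fold changes of 3.69 and 2.25, but each overlaps a gene on the opposite strand. GLIS2-AS1 rested on 1, 0 and 0 counts against 8, 5 and 4. Without vector replicate 1 its log2 fold change was 5.56, and without vector replicate 2 its adjusted p was 0.0537, the highest over the alternatives.

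Among the genes with the largest decreases, OVOL2, a transcriptional repressor that maintains the epithelial state, fell from 1.39 ± 0.188 to 0.380 ± 0.0815 FPKM, and was 3.48-fold lower (edgeR adjusted p = 2.23e-05). OVOL2 overlaps SNX5 on the same strand and MGME1 on the other. GALNT3, an enzyme that starts mucin-type O-glycosylation, had a log2 fold change of -1.92, and the sortilin-family receptor SORCS2 one of -1.62. ITPR2, a calcium release channel, fell from 8.73 ± 0.547 to 3.47 ± 0.367 FPKM. PRSS1, cationic trypsinogen, fell to a mean of 7.82 FPKM from 22.3 (log2 fold change -1.43, standard error 0.11), but close trypsinogen copies lie beside it, and the processed pseudogenes RPL39P15, CCT7P2 and XPOTP1 can share reads with their parent genes. RPL39P15 (-1.57) lost its call without vector replicate 2 (adjusted p = 0.142), without vector replicate 3 (0.116) and without TIPE replicates 1, 2 or 3 (0.0764, 0.124 and 0.0876), within a range of 0.00201 to 0.142 over the alternatives. The noncoding LINC01976 (-1.57) lost its call without vector replicates 2 or 3 (0.0882 and 0.0793) and without TIPE replicates 2 or 3 (0.0777 and 0.0676), within a range of 0.00231 to 0.0882 over the alternatives.

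Of 42 genes listed as secreted factors that recruit macrophages or polarise them to an M2 state, 17 were measured. Of these, 12 rose, 2 fell (ANXA1 and VEGFA) and 3 did not pass. Adjusted over the list alone, 12 rose and 3 fell. The list median was 0.53, or 0.32 after quantile normalization, and camera called the list higher (adjusted p = 5.05e-07, and 0.0468 with an estimated correlation). ANGPT2, angiopoietin-2, rose from 1.39 ± 0.101 to 4.24 ± 0.167 FPKM, and the chemokine CXCL8, interleukin-8, from 5.56 ± 0.372 to 15.5 ± 1.89 FPKM (SD, n = 3 each). CCL20, a chemokine that binds CCR6, rose 3.21-fold to 4.41 ± 0.313 FPKM. GDF15, a stress-induced member of the TGF-beta superfamily, rose from 73.1 ± 2.78 to 113 ± 7.41 FPKM. CXCL1 rose 4.39-fold to 3.75 ± 0.228 FPKM, and the remaining risers were CXCL2, CX3CL1, CCL24, MIF, LGALS1, LGALS3 and TGFB1. ANXA1, annexin A1, and the angiogenic factor VEGFA had log2 fold changes of -0.74 and -0.34. The other listed genes lay under the expression filter, among them IL6, CCL5 and CXCL12 at 0 FPKM in both groups. PTGS2 and IDO1, listed there although they encode enzymes, were also at 0 FPKM. CSF1 went from 0.236 to 0.304 FPKM and CCL2 from 0.0086 to 0.049 FPKM. Neither passed in edgeR without the filter (adjusted p = 0.435 and 0.487). In edgeR without the filter EDN1 fell (log2 fold change -1.62, adjusted p = 0.00196). CSF2, whose groups overlapped, and TGFB2 rose (3.31 and 2.16, adjusted p = 0.00451 and 0.0159).

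Of 23 measured NF-kappaB target genes, 12 rose, 1 fell (CYLD, a deubiquitinase that restrains the pathway) and 10 did not pass, with the same counts adjusted over the list alone. The list median was 0.34, or 0.14 in limma on log2(FPKM + 1), and the list was called higher (camera adjusted p = 2.30e-06, and 0.0468 with an estimated correlation). TNFAIP2, CXCL8, CCL20 and CXCL3 had the smallest adjusted p, with log2 fold changes of 2.62, 1.55, 1.68 and 1.36. The chemokines CXCL1, CXCL2, CXCL8 and CCL20 belong to this list and to that of the macrophage factors. The feedback inhibitor NFKBIA had a log2 fold change of 0.14 and did not pass, while TNFAIP3, another inhibitor, rose with one of 0.47. Of 19 measured ERK/MAPK output genes, 12 rose, 3 fell (SPRED1, EPHA4 and DUSP4) and 4 did not pass. Adjusted over the list alone, 12 rose and 4 fell. The median was 0.23 and the list was called higher (camera adjusted p = 0.000378), but not with an estimated correlation (adjusted p = 0.0995) or after quantile normalization (median 0.08, adjusted p = 0.337, the highest over the alternatives). The ERK phosphatases DUSP5 and DUSP6 rose from 14.2 ± 0.441 to 33.3 ± 1.09 and from 34.4 ± 1.78 to 62.7 ± 3.41 FPKM. EMP1 had a log2 fold change of 0.56 and IER3 one of 0.38, which was -0.018 after quantile normalization.

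**Figure D4:**
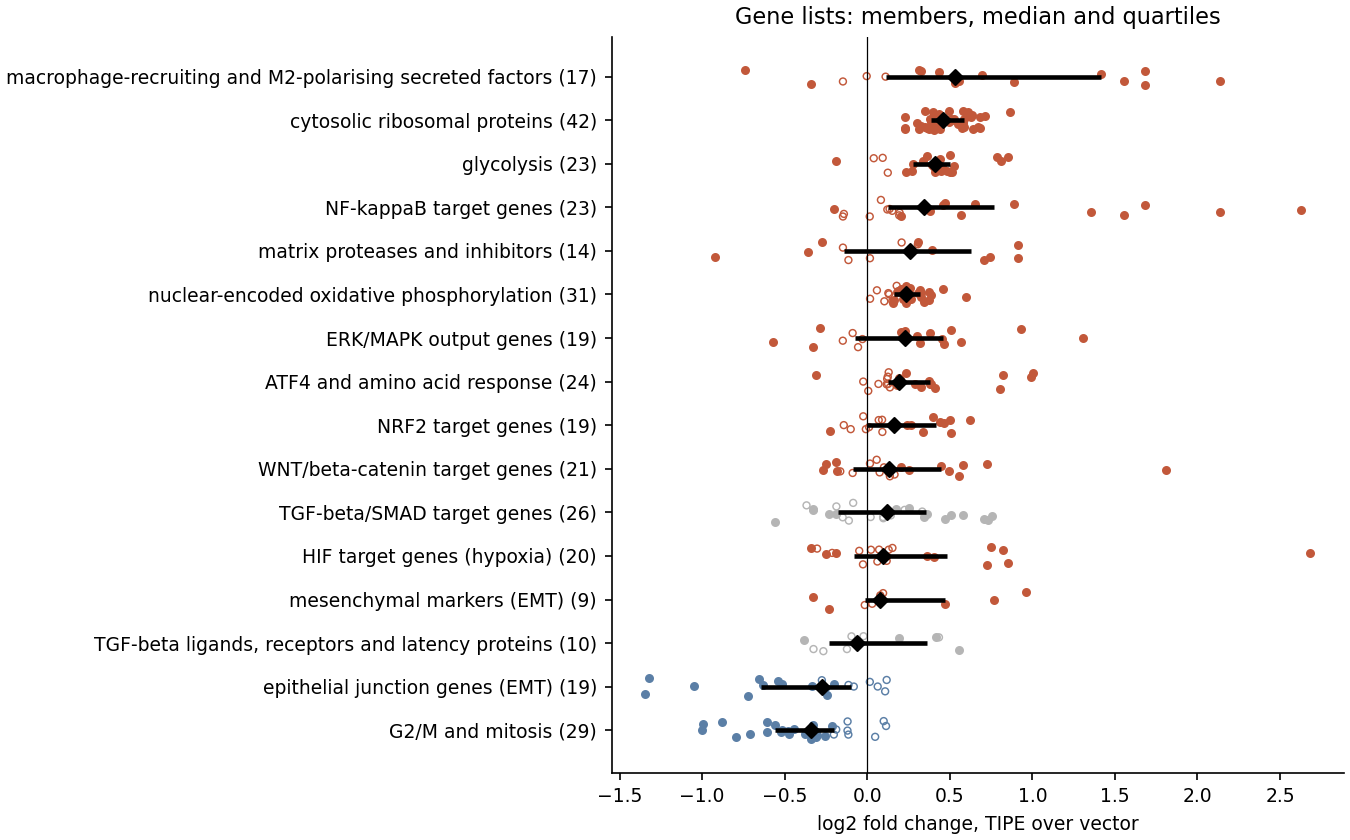
Log2 fold change (TIPE over vector, x axis) of every measured member of the 14 lists that camera called and of both TGF-beta lists, with the number of measured members in brackets. Filled points passed the threshold, diamonds are list medians and bars span the quartiles; red lists were called higher, blue lists lower and grey lists not called, and the medians run from -0.34 for mitosis to 0.53 for the macrophage factors.

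Of 19 measured epithelial junction genes, 12 fell, none rose and 7 did not pass, with the same counts adjusted over the list alone. The list median was -0.28 and the list was called lower (camera adjusted p = 3.29e-08, and 0.0468 with an estimated correlation). CDH1 (ENSG00000039068, chromosome 16, 68737292 to 68835537), E-cadherin of the adherens junction, fell from 35.9 ± 1.31 to 13.7 ± 0.875 FPKM (SD, n = 3 each). Its log2 fold change was -1.32 with a standard error of 0.06 (edgeR adjusted p = 4.08e-12). ESRP1, a splicing regulator of epithelial cells, fell from 21.9 ± 0.985 to 10.1 ± 0.179 FPKM. The tight junction protein MARVELD3, which overlaps PHLPP2 on the opposite strand, had a log2 fold change of -1.35, and desmoplakin (DSP) one of -0.52. Of 9 measured mesenchymal markers, 3 rose, 2 fell (FN1 and SNAI2) and 4 did not pass, with the same counts adjusted over the list alone. Camera called this list higher (adjusted p = 0.0323), but not with an estimated correlation (adjusted p = 0.179) or without vector replicate 1 (adjusted p = 0.0536; 0.00463 to 0.321 over the alternatives). Its median of 0.08 was -0.05 with each library rescaled to the same FPKM total. Vimentin (VIM) rose from 35.6 ± 0.580 to 66.0 ± 5.33 FPKM, S100A4, a calcium-binding protein, from 171 ± 7.82 to 277 ± 24.8 FPKM, and the fibronectin receptor subunit ITGA5 had a log2 fold change of 0.47. Fibronectin (FN1) had one of -0.23, which did not pass without vector replicate 1 (adjusted p = 0.0544) or without TIPE replicate 3 (-0.13, adjusted p = 0.0508) and was 0.014 with the GC and length trend removed (adjusted p over the alternatives, 0.00232 to 0.889). Under the filter, PRRX1 of the same list fell from 0.393 ± 0.0101 to 0.140 ± 0.0312 FPKM (edgeR without the filter, adjusted p = 6.23e-07).

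Of 14 measured matrix proteases and inhibitors, 6 rose and 3 fell, with the same counts adjusted over the list alone, and the median was 0.26. The camera call (adjusted p = 0.0392) was lost with an estimated correlation (adjusted p = 0.179), with a replicate block (0.0542) and without vector replicates 1, 2 or 3 (0.0536, 0.0566 and 0.0542), and it ranged from 0.00670 to 0.337 over the alternatives. SERPINE2, a protease inhibitor, the lysosomal protease CTSB and the metalloprotease inhibitor TIMP3 had log2 fold changes of 0.91, 0.74 and -0.92. ADAM10 and ADAM17 were the others that fell.

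Of 29 measured genes of G2/M and mitosis, 21 fell, none rose and 8 did not pass, with the same counts adjusted over the list alone. The median was -0.34 and the list was called lower (camera adjusted p = 1.37e-10, and 0.0468 with an estimated correlation). The proliferation marker MKI67 fell from 14.4 ± 0.519 to 7.48 ± 1.05 FPKM, and TOP2A, topoisomerase II alpha, from 33.9 ± 1.08 to 21.2 ± 0.348 FPKM. CENPF, a kinetochore protein, fell from 6.14 ± 0.557 to 2.93 ± 0.170 FPKM, and KIF11, a spindle motor, had a log2 fold change of -0.79. Of 30 genes of S phase and DNA replication, 10 rose and 5 fell, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.315). With the GC and length trend removed 8 rose and 7 fell. Of these genes, the helicase subunits MCM5 and MCM6, the polymerase subunit POLD1 and the thymidylate synthase gene TYMS had log2 fold changes of 0.50, 0.35, 0.42 and 0.44.

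All 42 cytosolic ribosomal protein genes rose, also when adjusted over the list alone, with a median log2 fold change of 0.46, or 0.14 after quantile normalization, and a range from 0.23 to 0.87. The camera adjusted p was 6.44e-32 at the preset correlation. With the estimated correlation the call was lost (adjusted p = 0.179). RPS9, RPS14, RPS15 and RPL18 had the smallest adjusted p, and RPS9 rose from 73.9 ± 3.11 to 128 ± 5.31 FPKM (SD, n = 3 each). Processed pseudogenes of this family can share its reads, so single members are uncertain.

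Of 23 measured glycolysis genes, 19 rose, 1 fell (PFKFB3) and 3 did not pass, with the same counts adjusted over the list alone and a median of 0.41, or 0.21 after quantile normalization. The call (camera adjusted p = 4.03e-10) was lost with an estimated correlation (adjusted p = 0.179). The lactate exporter SLC16A3 rose from 9.17 ± 0.402 to 15.0 ± 0.261 FPKM and GAPDH, which has many pseudogenes, from 1047 ± 47.1 to 1408 ± 45.6 FPKM. The log2 fold change of GAPDH was 0.50, or 0.015 after quantile normalization (adjusted p = 0.640, the highest over the alternatives). HK1, hexokinase 1, had a log2 fold change of 0.52 and glucose-6-phosphate isomerase (GPI) one of 0.50. Of 31 nuclear-encoded genes of oxidative phosphorylation, 22 rose and none fell (adjusted over the list alone, 25 and none), with a median of 0.23, or 0.093 with each library rescaled to the same FPKM total. Their call (camera adjusted p = 3.51e-06) was also lost with an estimated correlation (adjusted p = 0.196). COX4I1, a cytochrome c oxidase subunit, had a log2 fold change of 0.60, and the complex I subunits NDUFV1, NDUFA1 and NDUFS3 had log2 fold changes of 0.39, 0.35 and 0.37.

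Several stress and nutrient lists were also called higher, each of them not in the camera version with an estimated correlation. That version also has fewer degrees of freedom. Its estimates were 0.0016 for HIF, 0.10 for ATF4, 0.024 for NRF2 and -0.012 for WNT targets, against the preset 0.01. Of 20 measured HIF target genes, 7 rose and 3 fell (VEGFA, ERO1A and PFKFB3), or 9 and 4 adjusted over the list alone, with a median of 0.09. Its adjusted p was 0.00301, or 0.144 with an estimated correlation and 0.114 in limma on log2(FPKM + 1) (8.27e-05 to 0.192 over the alternatives), and its median was -0.04 with each library rescaled to the same FPKM total. NDRG1, DDIT4, an inhibitor of mTORC1, the carbonic anhydrase CA9 and PFKFB4 had log2 fold changes of 2.68, 0.82, 0.75 and 0.85. Of 24 genes of the ATF4 and amino acid response, 14 rose and 1 fell (CEBPG), or 17 and 1 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 2.13e-05, or 0.179 with an estimated correlation). The glutamine transporter SLC1A5 rose from 141 ± 5.17 to 234 ± 7.48 FPKM, and NUPR1 and the serine synthesis enzyme PHGDH had log2 fold changes of 0.99 and 0.41. Of 19 NRF2 target genes, 9 rose and 1 fell (ABCC3), also when adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0109, or 0.179 with an estimated correlation). AKR1C3, a ketosteroid reductase, the transketolase TKT and NQO1, a quinone reductase, had log2 fold changes of 0.62, 0.50 and 0.47. Of 21 WNT/beta-catenin target genes, 8 rose and 4 fell (ZNRF3, TCF7, EPHB2 and LGR5), or 9 and 5 adjusted over the list alone, with a median of 0.13 that was -0.02 with each library rescaled to the same FPKM total. Camera called this list at an adjusted p of 0.0347, which was 0.179 with an estimated correlation, 0.0655 without vector replicate 3 and 0.198 with the GC and length trend removed (0.00177 to 0.325 over the alternatives). APCDD1, ASCL2, SP5 and NOTUM had the smallest adjusted p, with log2 fold changes of 0.72, 0.58, 0.55 and 0.50.

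**Figure D5:**
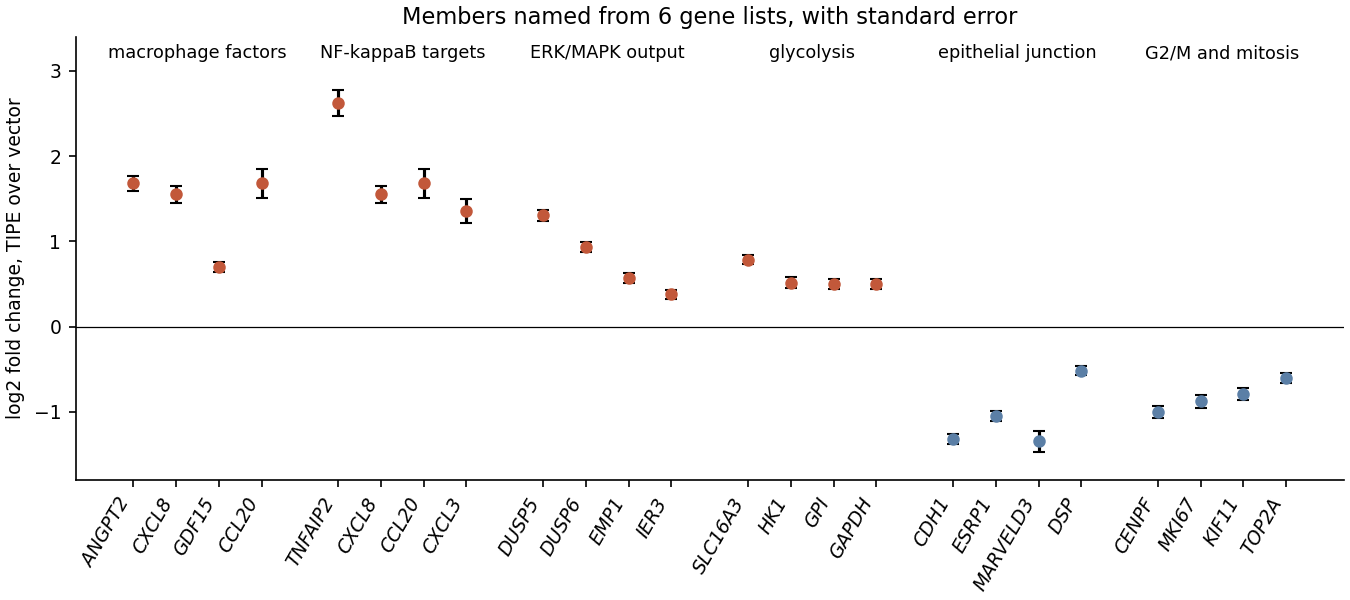
Log2 fold change (TIPE over vector, y axis) of the members named from 6 gene lists, with bars of 1 standard error from edgeR; CXCL8 and CCL20 belong to both the macrophage and the NF-kappaB list and are drawn in each. All plotted members passed the threshold, from TNFAIP2 at 2.62 to MARVELD3 at -1.35.

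Most markers of other cell types lay under the expression filter. Of 20 macrophage markers, 2 were measured (LAPTM5 and CD14), at 0.425 and 0.501 FPKM in vector libraries, and neither passed (edgeR adjusted p = 0.0697 and 0.985; LAPTM5 at 0.0432 without TIPE replicate 2 and at 0.235 or less over the alternatives). Of 14 lymphocyte markers, 3 were measured. CD4 rose from 0.709 ± 0.0531 to 1.20 ± 0.0467 FPKM, CD8A had a log2 fold change of 0.88 that did not pass without vector replicate 2 (adjusted p = 0.0670) or without TIPE replicate 2 (0.109; 0.00111 to 0.122 over the alternatives), and TRAC did not pass. Of 15 fibroblast markers, 3 were measured and S100A4 and FBLN1 rose, FBLN1 to 2.25 ± 0.0262 FPKM. Under the filter, PDGFRB, a receptor for platelet-derived growth factor, went from 0.239 ± 0.0897 to 0.535 ± 0.0219 FPKM (edgeR without the filter, adjusted p = 3.16e-07). Of 10 endothelial markers, only EGFL7 was measured, at 2.93 ± 0.366 and 2.87 ± 0.159 FPKM (edgeR adjusted p = 0.808). Mitochondrial genes took 5.92% to 7.06% of the counts in each library, with overlapping groups. Of 13 mitochondrially encoded transcripts, MT-CO1 alone passed, and none did when adjusted over the list alone (camera adjusted p = 0.892). MT-CO3 and MT-CO2 had log2 fold changes of 0.13 and 0.15 and did not pass, but did without vector replicate 3 (adjusted p = 0.0287 and 0.0303) and without TIPE replicate 3 (0.0434 and 0.00975). Over the alternatives their adjusted p reached 0.964 and 0.925. Of 8 measured replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, 4 fell and none rose, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.149), but was with the GC and length trend removed (median -0.46, adjusted p = 0.0318). H2BC12 and H2AC6 had log2 fold changes of -0.48 and -0.36. H1-2 (-0.25) passed with all libraries, but not without vector replicates 1 or 2 (adjusted p = 0.0620 and 0.0901) or TIPE replicate 1 (0.134), over a range of 0.00191 to 0.134. H1-4 (-0.84) did not pass without vector replicates 1 or 2 (0.0547 and 0.271) or TIPE replicates 1, 2 or 3 (0.125, 0.0578 and 0.0709), over a range of 0.0116 to 0.271.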

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

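Removal of the GC or GC and length trend, DESeq2, library totals without factors and protein-coding genes alone were chosen after the data were seen. Over the 24 alternatives, 3887 of 4037 values for the 170 named genes kept their direction and their side of the threshold. Of the others, 138 no longer passed, 7 passed in addition and 5 changed sign, none of them passing in the new direction. For the gene lists 813 of 874 values kept both, 50 no longer passed and 11 passed in addition. Most of the named genes were chosen for a small adjusted p or a large fold change in these same data. Their stability was therefore largely built in and does not stand for that of all genes. Of the 5903 genes past the threshold, 3780 were shared with the fit with GC and length trends removed. With median-ratio size factors in edgeR, 5888 were shared. The lists of macrophage factors, NF-kappaB targets, epithelial junction, mitosis, glycolysis, oxidative phosphorylation and ribosomal proteins were called in all 23 alternatives that gave list tests, but their medians came down to 0.14 for ribosomal proteins, 0.093 for oxidative phosphorylation, 0.13 for NF-kappaB targets, 0.21 for glycolysis and 0.32 for macrophage factors. These calls are at the preset correlation, and with an estimated one those of ribosomal proteins, glycolysis and oxidative phosphorylation were lost (adjusted p = 0.179, 0.179 and 0.196). Directional fry passed these lists (fry adjusted p = 0.00135, 0.00163 and 0.00235). It also passed lists that camera did not call, such as integrins (0.0110). The WNT and protease lists were each lost in 14 alternatives and the mesenchymal list in 11. The HIF list was lost in 8, and the ERK/MAPK, ATF4 and NRF2 lists were lost after quantile normalization alone (adjusted p = 0.337, 0.0519 and 0.135). The number of genes past the threshold ranged from 4495 (without vector replicate 2) to 6493. DESeq2 called 5175 genes, 5160 of them shared with edgeR.

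The number of higher genes, 2967, was 1911, 1908 and 1902 in limma with pseudocounts of 1, 0.5 and 0.1, 1789 with trend=FALSE and 1308 on log2(TPM + 1). With library totals and no factors 2137 were higher and 3880 lower. The 205 genes changed at least 2-fold were 53 and 98 in limma with pseudocounts of 1 and 0.5, where a pseudocount shrinks the folds of low genes. With further limma settings on log2(FPKM + 1) they were 53 with median-ratio scaling, 52 with quantile normalization, 48 with trend=FALSE and 60 with array quality weights. In edgeR they were 478 with no expression filter, 127 at a mean FPKM of at least 1 and 136 among protein-coding genes, where other genes were tested. In the same order, 38, 60, 43, 45, 35, 36, 310 and 84 of these were higher (71 on log2(TPM + 1)), and 15, 38, 10, 7, 13, 24, 168, 43 and 34 were lower. Without each library in turn, 54 to 108 genes were at least 2-fold lower, the most without TIPE replicate 1. Lists called higher numbered 5 after quantile normalization, and lists called lower numbered 4 with no expression filter. The causes of the other changes were not tested.

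TGFB2 rested on 34 counts in all, and whether depth limited its calls was not tested. In limma its log2 fold change was 0.091, 0.17 and 0.63 with pseudocounts of 1, 0.5 and 0.1, 0.095 with median-ratio scaling, 0.10 with quantile normalization, 0.26 on log2(TPM + 1), 0.091 with trend=FALSE and 0.11 with array quality weights. In edgeR it was 1.66 to 2.58 without each library in turn. Median-ratio size factors in place of TMM in edgeR changed the call of no named gene. DESeq2 gave no adjusted p for TGFB2, and the filter at a mean FPKM of 1 removed it with TGFB3, TNFAIP8L2 and TNFAIP8L3. DESeq2 gave no list tests. The log2 fold changes of LTBP4 (-0.025 with the GC trend removed) and FN1 (0.014 with the GC and length trend removed) changed sign. So did those of KRT8, IER3 and GSTP1 (-0.0076, -0.018 and -0.070 after quantile normalization). None passed in the new direction (edgeR adjusted p = 0.792 and 0.889, limma adjusted p = 0.860, 0.650 and 0.139), and the cause was not tested.

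Replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.0051, -0.024 and -0.055. With a replicate block 5599 genes passed, 5558 of them shared with the fit without it. Among named genes and lists the block changed the calls of RPL39P15, LINC01976, H1-4 and the matrix proteases alone.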

Other observations

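The tests of chromosome 7 copy number, of an equal change along that chromosome and of reads lost from long mitosis genes were chosen only after the result was seen, as was the removal of GC and length trends as an alternative. Cytokines and growth factors outside the macrophage list went both ways, with 9 of 25 higher and 7 lower (11 and 8 adjusted over the list alone; camera adjusted p = 0.315). CXCL3, the WNT antagonist DKK1, PDGFA and CXCL16 had log2 fold changes of 1.36, 1.81, 0.39 and -0.45. Of 10 intestinal epithelial markers, 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.681). CDX2, an intestinal transcription factor, KRT18 and KRT8 had log2 fold changes of 0.92, 0.71 and 0.36, KRT8 at -0.0076 after quantile normalization, against -1.32 for CDH1. Of 15 stem and progenitor markers, 5 rose and 5 fell, also when adjusted over the list alone, with a median of 0.02, a mean of -0.0047 and a test leaning higher (camera adjusted p = 0.876). CD24 and ASCL2 had log2 fold changes of 0.83 and 0.58, and ALCAM and SOX2 of -1.23 and -0.72. Of 16 collagen and laminin genes, 4 rose and 4 fell (camera adjusted p = 0.913). The laminin chains LAMA3 and LAMB3 had log2 fold changes of -0.72 and -0.31, and LAMB2 and COL7A1 of 0.45 and 0.70. Of 13 integrins, 6 rose and 1 fell, ITGA3 (camera adjusted p = 0.259; called higher at 0.0479 with the GC and length trend removed), and ITGA7 and ITGB7 had log2 fold changes of 0.74 and 0.88. These counts for collagens, laminins and integrins were the same adjusted over the list alone. Of 17 YAP/TAZ targets, 4 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.876), with CRIM1 at 1.82 and TEAD1 at -0.58.

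Of 19 genes of phosphoinositide and AKT signalling, 9 fell and 2 rose, also when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0889; 0.0343 without TIPE replicate 1). The kinase subunits PIK3CA and PIK3CD had log2 fold changes of -0.44 and 0.74, and the phosphatase PHLPP2 one of -0.43. With the GC and length trend removed, 3 of these genes fell and 2 rose, the median was -0.063 (camera adjusted p = 0.523) and PIK3CA did not pass (adjusted p = 0.219). Of 13 heat shock genes, 5 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.0535; 0.0241 without TIPE replicate 1), with HSPA8 at 0.46 and DNAJB1 at 0.39. With the GC and length trend removed 5 of them rose and 2 fell, and the median went from 0.15 to 0.071. HSPA8 was at 0.078 after quantile normalization (limma adjusted p = 0.0930). Interferon-stimulated genes had 6 of 18 higher and 2 lower (camera adjusted p = 0.329; ISG15 0.65, IFI35 1.01), and MHC class I genes 4 of 15 higher and 2 lower (0.377; PSMB10 0.66, PSMB9 0.90), with the same counts adjusted over each list alone. With the GC and length trend removed the balance of the MHC class I genes turned, to 2 higher and 4 lower. Immediate early genes had 8 of 21 higher and 4 lower, also adjusted over the list alone (0.315; NR4A2 0.79, EGR1 -0.35), but 4 higher and 8 lower with the GC and length trend removed, where the median went from 0.09 to -0.13. Of 19 p53 targets, 9 rose and 2 fell (9 and 3 adjusted over the list alone; 0.224), and of 28 apoptosis regulators 9 rose and 5 fell (11 and 5; 0.377), with the BH3-only genes BBC3 and BMF at 0.89 and 1.34 and the inhibitor XIAP at -0.41. With the GC and length trend removed 5 p53 targets rose and 2 fell, and their median went from 0.12 to 0.046. Of 10 CDK inhibitors and senescence genes, 2 rose and 2 fell (2 and 3; 0.610), with RB1 at -0.57 and CDKN2A at 0.31. With the GC and length trend removed none rose and 3 fell, with CDKN2A at 0.10 (adjusted p = 0.147). Of the other members that passed, GLB1 did not without vector replicates 2 or 3 or TIPE replicates 1 or 2 (adjusted p = 0.0812, 0.0742, 0.0755 and 0.120). CDKN2C did not without vector replicates 1, 2 or 3 or TIPE replicates 1 or 2 (0.0913, 0.0523, 0.118, 0.158 and 0.146). The unfolded protein response had 6 of 21 higher and 3 lower (7 and 3; 0.737; HERPUD1 0.42, SEL1L -0.42), cholesterol synthesis 9 of 24 and 3 (10 and 3; 0.402; NSDHL 0.59, SC5D -0.38; 5 and 1 with the GC and length trend removed, SC5D then at -0.14, adjusted p = 0.0717) and fatty acid synthesis and uptake 6 of 17 and 4 (7 and 4; 0.708; ACSL5 1.16, CPT1A -0.55). With that trend removed, fatty acid synthesis and uptake had 3 higher and 3 lower and the unfolded protein response 4 and 4. Drug transporters and enzymes had 5 of 10 higher and 2 lower (0.377; SULT1A1 0.55, SULT2B1 -1.36, and GSTP1 0.29, or -0.070 after quantile normalization), and immune checkpoint ligands 2 of 7 higher and 3 lower (0.875; VSIR 0.78, ENTPD1 -0.43), also when adjusted over each list alone. ENTPD1 did not pass in 6 of its 24 alternatives (adjusted p up to 0.176), at -0.21 with the GC and length trend removed.

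Fold changes followed GC content, with a Spearman rho across 14102 genes, which are not independent replicates, of 0.416, and followed exonic length with a rho of -0.221. If GC content and length bias were the whole reason for a list's call, its median should fall to under 50% and its call end once each library's trend is removed. Of the 14 called lists, 7 were tested so, and each kept its camera call at the preset correlation, with medians of 0.44 for ribosomal proteins, 0.21 for oxidative phosphorylation, 0.33 for glycolysis, 0.28 for NF-kappaB targets, 0.32 for macrophage factors, -0.37 for mitosis and -0.29 for junction genes. Of the others, the ERK/MAPK, HIF, ATF4 and NRF2 lists kept their calls (adjusted p = 0.000256, 8.27e-05, 0.000102 and 0.0034), as did the mesenchymal and protease lists (0.0115 and 0.0150) although their medians went from 0.08 and 0.26 to 0.014 and 0.085, and the WNT list lost its call (0.198); with an estimated correlation and no trend removed, only the NF-kappaB, macrophage, mitosis and junction lists were called (0.0468 each). The trend itself may be technical or biological, which no test here separates, and an effect of TIPE stays a hypothesis, since each group may also be a single culture.

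Genes of chromosome 7 lay lower in TIPE libraries. Their median log2 fold change differed from that of all other genes by -0.106 after trend removal (762 genes, 64.4% below 0 against 50.1% elsewhere). The difference was -0.102 before it, so the GC and length trend that was removed does not account for the difference. Bias beyond that trend was not tested. The median deviation of the chromosome was 0.0446 to 0.0510 in vector libraries and -0.0527 to -0.0389 in TIPE libraries, and chromosomes 16, 17 and 19 lay above the other autosomes by up to 0.0727. Of 148 overlapping windows of 25 neighbouring genes, moved by 5 genes at a time, 126 lay below 0. The other 22 all began at 106 Mb or beyond. The last 191 of the chromosome's genes lay above its first 190 by 0.119 in median (95% bootstrap interval 0.0431 to 0.192). An equal change of the whole chromosome in a share of the cells would give no such difference. The comparison was chosen after the result was seen and its interval treats genes as independent, so it argues only weakly against that change. A change in copy number of part of chromosome 7 stays open. The smaller difference of its sides of 60 Mb was -0.0900, but the chromosome was chosen for lying lowest, so this value decides nothing.

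Within the mitosis list, longer genes fell more, with a Spearman rho of -0.692 between exonic length and trend-corrected fold change across 29 genes (two-sided permutation p = 2e-05). The length trend over all genes had been removed (rho of -0.0097 with exonic length afterwards), so loss of reads from long genes could give such a slope only beyond that trend. The 15 shorter genes still had a median of -0.28 (95% bootstrap interval -0.38 to -0.16), against -0.43 for the longer ones. A loss beyond the trend may thus add to the decrease of the longest members, while slower division of the TIPE cells stays open and was not tested.

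Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes past the threshold, the real split with 5903. The highest of the others gave 0, and 10 splits are too few for a share under 0.05. Each of the others mixed vector and TIPE libraries, so the difference between the groups entered the spread within them. Their counts therefore do not measure false calls.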
